A study of Caenorhabditis elegans with 12 samples.

How the data were processed

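Poly(A) RNA from whole Caenorhabditis elegans adults was sequenced in 12 libraries, with 3 libraries labelled as biological replicates in each of 4 groups. The groups crossed genotype, wild type N2 or sek-1(km4), with diet, ad libitum feeding (AL) or dietary restriction (DR). SEK-1 is a MAP kinase kinase of the p38 immune pathway, and km4 is a deletion allele of its gene. Per the labels' protocols, worms were moved to liquid medium on adult day 3 and collected on adult day 6, after 3 days on the diet at 20 °C. Food was the Escherichia coli strain OP50, arrested in growth, at an optical density of 3 for AL and 0.1 for DR, with 10 to 20 worms in each well of 1 ml. The medium held 100 mg/L of fluorodeoxyuridine (FUdR), which blocks the production of progeny. Reads were 50 bp single-end.

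The deposited table holds 1 whole-number read count per gene and library, not normalized, and the counts were made with featureCounts of the Subread package, per the submitters' processing notes. The aligner, the genome build, the annotation, the strand setting and the versions of these tools are not given in the sources used here. The table has 46748 gene identifiers and 12 columns of counts, all 12 of which name a sample by its title, and it has 0 lines that name no gene. A symbol was found for 43693 identifiers, 46449 identifiers are in the Ensembl 115 annotation of WBcel235, and 2703 were labelled by sequence name. Gene length, biotype and location were taken from that annotation. No pair of libraries held identical counts. Near-identical gene copies can share or split reads under the counting used, and values of such genes are given as uncertain.

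Total counts ranged from 13673987 to 31675540 per library. Ribosomal RNA (22 annotated genes and 1 repeat pseudogene) took 32.63% to 50.95% of the counts, with 95% binomial intervals (Wilson) of at most 0.0265% to either side, so that 7187373 to 19688057 counts per library remained for other genes. The limit that a count of 0 allows was set at 3 counts, which is 0.095 to 0.219 counts-per-million (CPM) by library. It is taken on the library total, without the normalisation applied to the CPM values below, so genes near it are placed only roughly. Such intervals and limits cover counting error only.

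Genes were tested with edgeR 4.0.16 in R 4.3.3. Normalisation was TMM, and filterByExpr with its minimum count of 10 left 14611 genes. All 12 libraries entered 1 quasi-likelihood fit with robust dispersion estimation and a mean per group, without a replicate term, so that the 4 groups shared 1 estimate of the spread. The 5 contrasts were DR against AL in each genotype, sek-1(km4) against N2 on each diet, and the genotype by diet interaction. A gene passed when its Benjamini-Hochberg adjusted p over all tested genes was under 0.05. Standard errors of log2 fold changes (SE) are the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM values are TMM-scaled and given as mean ± SD of the 3 libraries of a group.

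Lists of genes were tested with limma 3.58.1 (camera, preset correlation of 0.01), with Benjamini-Hochberg adjustment over 42 lists and 5 contrasts together, 210 tests in all. The same lists were tested with an estimated correlation and with fry. Of the 76 list calls, 1 held with an estimated correlation and 17 held with fry. Of these calls 0 had a median or mean of the opposite sign to the test, while 26 of the tests that were not called did. The lists covered p38 pathway components (sek-1 left out), p38-dependent immune effectors, C-type lectins, lysozymes, epidermal antimicrobial peptides, saposin-like proteins and pals genes. They also covered DAF-16 targets in both directions, insulin-like peptides, SKN-1 and phase II genes, glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450s, flavin-containing monooxygenases, cytosolic heat shock genes and unfolded protein response genes. Metabolic lists were lysosomal lipases, fatty acid beta-oxidation, fatty acid synthesis, vitellogenins, autophagy, lysosomal proteases, vacuolar ATPase subunits, the glyoxylate cycle, trehalose and glycogen metabolism, glycolysis, the propionate shunt, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. Ribosomal proteins, proteasome subunits, histones, collagens, regulators reported for lifespan under DR, and markers of germ line, eggshell, sperm, body wall muscle, pharynx, intestine and neurons completed them. The lists overlap in part.

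The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes sek-1 in every library, and for each contrast the genes with the largest log2 fold changes among those that passed, had a mean of at least 5 CPM over the 12 libraries and had no overlap between the libraries of the groups compared (10 each way for DR in N2 and for genotype on AL, 6 each way for the other contrasts, with no overlap rule for the interaction). It also takes up to 4 members with the smallest p of each called list, the 5 smallest p of the interaction, and always sysm-1 (T24B8.5), irg-4, irg-5, clec-67, lys-2, acs-2, fat-7, sod-3, mtl-1, lipl-4, vit-2, gst-4, ins-7, pmk-1, hlh-30, daf-16, skn-1 and pha-4.

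Settings listed in advance were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, fits of only the 6 libraries compared, and each library left out in turn. A further 6 settings were chosen after seeing the data. These were rRNA genes left out, limma voom with sample quality weights, offsets that remove a trend with exon length in each library, the block together with those offsets, N2_AL 3 and N2_DR 3 both left out, and all 4 libraries numbered 3 left out. For comparisons that share libraries, 20 sets of unchanged groups were simulated.

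The fits were tested on simulated counts with 66 or 67 genes changed by each of 3 known folds. For DR in N2, where 14269 simulated genes were tested, the edgeR fit recovered 19.4% of genes changed 2-fold and 83.3% of those changed 4-fold.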

Results

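Transcript levels were measured in day 6 adult worms of 4 groups, wild type N2 and sek-1(km4) mutants on full food (AL) or diluted food (DR), with 3 libraries per group. SEK-1 is the MAP kinase kinase that acts between NSY-1 and the p38 kinase PMK-1 in the pathogen response. Total counts were 31675540, 23182296 and 13673987 in N2_AL replicates 1 to 3, 23066791, 26893867 and 25414211 in N2_DR, 27860858, 23930332 and 19538479 in sek1_AL, and 24422622, 22516184 and 17704397 in sek1_DR. Ribosomal RNA took 45.4% ± 6.79 (SD, n = 3) of the counts in N2_AL, 36.8% ± 1.43 in N2_DR, 36.2% ± 0.28 in sek1_AL and 37.6% ± 6.56 in sek1_DR.

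The first principal component of the 5000 most variable genes held 56.6% of the variance and separated the genotypes, with N2 libraries between −68.23 and −25.89 and sek-1(km4) libraries between 36.63 and 66.86. The second component, with 22.7%, separated N2_AL replicate 3 at −115.6 from the other libraries. That library correlated with the other N2_AL libraries at r = 0.904 and 0.907 across genes (genes are not independent replicates), against 0.991 between those libraries and at least 0.98 within every other group. It held more of short transcripts and less of long ones than the other N2_AL libraries. Mitochondrially encoded mRNA made up 1.178% of its counts outside rRNA, against 0.307% and 0.476% in the other N2_AL libraries, and it had counts in 24108 genes against 18885 and 17856.

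**Figure D1:**
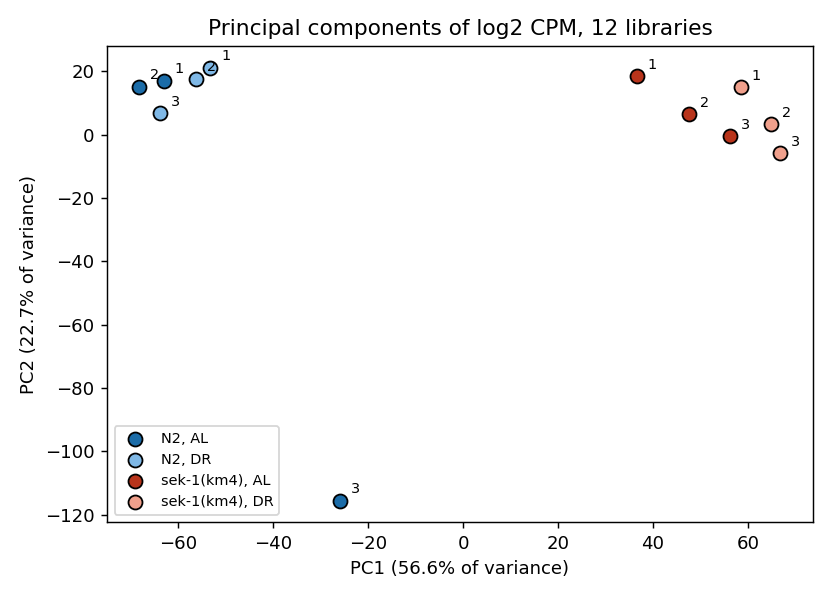
Principal components of log2 CPM of 5000 genes, with each of the 12 libraries as a point numbered by replicate and coloured by group. The horizontal axis (56.6% of variance) splits N2 from sek-1(km4), and N2_AL replicate 3 lies alone at −115.6 on the vertical axis (22.7%).

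**Figure D2:**
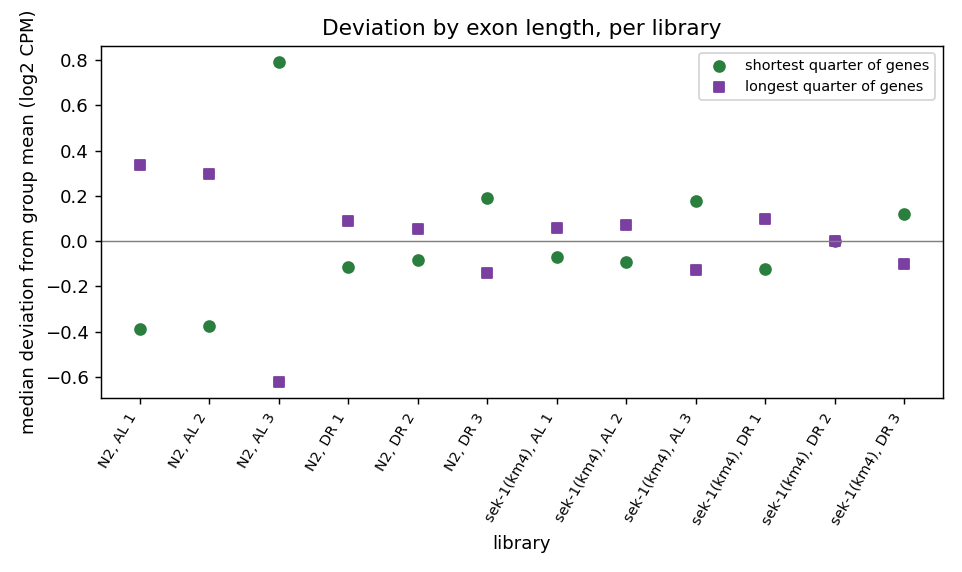
Median deviation from the group mean log2 CPM per library, for the shortest (circles, exon length up to 935.25 nt) and the longest (squares, from 2110.75 nt) of 13646 genes. N2_AL replicate 3 lies farthest from its group, at 0.791 for short genes and −0.624 for long genes.

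The sek-1 gene lies on chromosome X at 7816734 to 7821036 (WBcel235, in the Ensembl annotation named above), with an exon length of 2054 nt. Its level was 22.76, 20.81 and 3.716 CPM in the N2_AL libraries, 28.55, 23.96 and 23.42 CPM in N2_DR, 18.8, 16.39 and 17.44 CPM in sek1_AL, and 22.38, 21.25 and 20.76 CPM in sek1_DR. The sek-1 count did not differ by genotype past the threshold on AL (log2 fold change 0.14 ± 0.44 SE, n = 3 per group, edgeR adjusted p = 0.868) or on DR (−0.24 ± 0.44, edgeR adjusted p = 0.689). On AL its sign turned to −0.32 without N2_AL replicate 3. A count over the whole gene takes in reads from exons outside the deletion, so this level checks neither the deletion nor the strain labels. The known targets of the pathway did separate the strains, with median log2 CPM of 18 p38-dependent immune effectors at 2.92, 2.95 and 2.87 in N2_AL and at −2.04, −1.58 and −1.74 in sek1_AL.

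**Figure D3:**
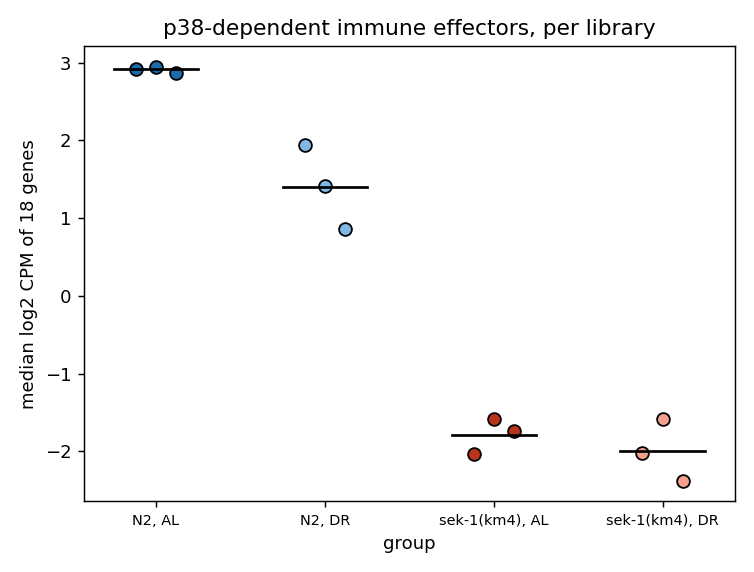
Median log2 CPM of 18 p38-dependent immune effectors in each library (points), with the mean of the 3 libraries of each group as a bar line. N2_AL lies at 2.87 to 2.95, N2_DR at 0.861 to 1.94, and the sek-1(km4) libraries lie between −2.38 and −1.58 on both diets.

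DR in wild type asked which transcripts 3 days of diluted food changed. The cathepsin B-like protease gene cpr-2 rose from 10.2 ± 1.97 to 185.5 ± 69.2 CPM (log2 fold change 4.18 ± 0.38 SE, n = 3 per group, edgeR adjusted p = 0.000871). The C-type lectin genes clec-60 (3.50 ± 0.49) and clec-52 (2.43 ± 0.25) rose, as did the aquaporin gene aqp-1 (2.22 ± 0.21), which went from 6.16 ± 1.42 to 28.4 ± 5.23 CPM. Genes that fell included the immune effector gene sysm-1 (T24B8.5), from 18.5 ± 10.0 to 0.523 ± 0.228 CPM (−5.13 ± 0.55, edgeR adjusted p = 0.00199), and the collagen gene col-94 (−4.24 ± 0.38, edgeR adjusted p = 0.000871). Among metabolic genes, cth-1, for cystathionine gamma-lyase, fell from 8.59 ± 1.34 to 1.07 ± 0.17 CPM (−2.995 ± 0.21, edgeR adjusted p = 0.00012), and the folate transporter gene folt-2 fell with a log2 fold change of −3.18 ± 0.46. Of 14611 genes tested, 53 rose and 106 fell in wild type on DR, and 45 and 101 of these changed at least 2-fold. The mean within-group variance over 3 (log2 CPM) was 0.24 in N2_AL, against 0.0495 in N2_DR, 0.0376 in sek1_AL and 0.0378 in sek1_DR. With 1 shared estimate of the spread, errors are probably too small for contrasts with N2_AL and too large for those without it. Gene counts therefore do not rank the contrasts.

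Further genes that rose in wild type on DR were C50F7.5 (2.19), R03H10.6 (1.51), cutl-8 (1.55), asp-12 (1.5), the lysosomal lipase gene lipl-4 (1.83 ± 0.34, edgeR adjusted p = 0.027) and the pair pud-1.1 (1.84) and pud-1.2 (1.80), near-identical copies whose separate values are uncertain. Further genes that fell were cnc-7 (−4.85 ± 0.78), F46F2.3 (−3.19), dct-16 (−2.46) and the collagen genes col-93 (−4.34), col-160 (−3.61), col-159 (−3.61), col-42 (−2.25) and col-95 (−2.22). Several genes reported in other starvation or longevity work did not pass on DR in wild type by edgeR. The acyl-CoA synthetase gene acs-2 stood at 1.28 ± 0.43 (adjusted p = 0.204), fat-7 at −0.77 ± 0.32 (0.317), sod-3 at −0.51 ± 0.37 (0.54), mtl-1 at −0.23 ± 0.44 (0.796) and the yolk protein gene vit-2 at −0.56 ± 0.49 (0.608). The values of gst-4 (−0.74 ± 0.42), ins-7 (−3.23 ± 1.26), pmk-1 (0.42 ± 0.17), hlh-30 (0.23 ± 0.27), daf-16 (0.17 ± 0.33), skn-1 (0.24 ± 0.31) and pha-4 (−1.29 ± 0.44) did not pass either.

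The p38-dependent effectors were lower as a group on DR in wild type, with a median log2 fold change of −0.96. Of 18 measured members 5 fell, 1 rose and 12 did not pass, and adjusted over the list alone 10 fell and 1 rose. The falls were sysm-1, irg-4 (near the limit of 3 counts on DR, so without a fold), cld-9 (−2.24 ± 0.23), C17H12.6 (−4.16) and the lysozyme gene lys-2 (−1.401 ± 0.29), and the member that rose was clec-60. The camera test of the list gave an adjusted p of 1.38e-11 (limma), and adjusted p = 0.0888 with an estimated correlation. Irg-5 (−0.89 ± 0.34) and clec-67 (−0.40 ± 0.83) did not pass. Of 7 p38 pathway components 1 rose (1 also adjusted over the list alone), the adaptor gene tir-1 at 1.298 ± 0.26, and the camera test placed the list higher (median 0.42, and 0.27 without N2_AL 3, limma adjusted p = 0.000515, and adjusted p = 0.903 with an estimated correlation).

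Of 125 collagen genes 11 fell, 0 rose and 114 did not pass on DR in wild type, with a median of −1.07 (−0.52 without N2_AL 3), and 34 fell and 1 rose adjusted over the list alone (limma camera adjusted p = 7.54e-19, and adjusted p = 0.903 with an estimated correlation). Of 14 epidermal antimicrobial peptide genes 5 fell (9 adjusted over the list alone), among them cnc-7, cnc-2 (−3.15 ± 0.65), cnc-4 (−2.02 ± 0.36) and nlp-33 (−1.71 ± 0.33), and the others did not pass (median −1.79, and −1.01 without N2_AL 3, limma camera adjusted p = 7.76e-11, and adjusted p = 0.903 with an estimated correlation). Cytochrome P450 genes had 4 of 50 members fall and 0 rise (10 fell adjusted over the list alone, and 9 of 51 over all genes without N2_AL 3), namely cyp-35C1 (−2.60), cyp-36A1 (−1.56), cyp-35A2 (−1.46) and cyp-37A1 (−1.24), with a list median of −0.36 (−0.12 without N2_AL 3). Limma camera gave an adjusted p of 0.000789, and adjusted p = 0.903 with an estimated correlation. Of 31 glutathione S-transferase genes 2 fell (3 adjusted over the list alone), gst-29 (−1.58) and gst-27 (−2.01). By limma camera the adjusted p was 0.00216, and adjusted p = 0.933 with an estimated correlation. Of 8 DAF-16 targets lowered by low insulin signalling, dod-19 fell (−1.97 ± 0.37; 2 fell adjusted over the list alone), and the list median was −1.21 (−0.31 without N2_AL 3). The camera test in limma had an adjusted p of 0.000329, and adjusted p = 0.903 with an estimated correlation.

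Other lists were called in wild type on DR with few or no members past the gene threshold, and none of these calls held with an estimated correlation. Markers of body wall muscle had a median of −0.69 with 0 of 20 passing (4 lower without N2_AL 3) and 7 lower adjusted over the list alone (limma camera adjusted p = 1.38e-05, and adjusted p = 0.903 with an estimated correlation). The pals genes ranked higher, with pals-26 (1.15 ± 0.20) the 1 of 30 that rose and 1 adjusted over the list alone (limma camera adjusted p = 0.0273, and 0.933 as the adjusted p with an estimated correlation). Lysosomal lipases ranked higher too, with lipl-4 the 1 of 7 that rose and 2 adjusted over the list alone (limma camera adjusted p = 0.0193, and adjusted p = 0.903 with an estimated correlation). Cytosolic heat shock genes ranked higher with 0 of 12 passing, over all genes and adjusted over the list alone (limma camera adjusted p = 0.0322, and adjusted p = 0.903 with an estimated correlation). The call for pals genes and for lipases ended without N2_AL 1 or N2_AL 2 (for pals genes also without N2_DR 1), and the heat shock call without N2_AL 2 or N2_DR 3. Without N2_AL 3 the medians rose from 0.32 to 0.75 for pals genes, 0.19 to 0.99 for lipases and 0.11 to 0.66 for heat shock genes. Histone genes had a median of −0.71 (0 of 71 passing and 0 adjusted over the list alone, limma camera adjusted p = 8.64e-12, and adjusted p = 0.933 with an estimated correlation), and −0.45 without N2_AL 3. Ribosomal protein genes had a median of −0.61 (0 of 81 passing, 0 adjusted over the list alone, limma camera adjusted p = 6.31e-07, and adjusted p = 0.933 with an estimated correlation), and 0.02 without it, with an adjusted p of 0.504. Histone levels went with the rRNA share of a library. They averaged 3.56, 3.86 and 3.38 log2 CPM in N2_AL 2, N2_AL 3 and sek1_DR 3, the libraries with most rRNA (50.95%, 47.44% and 45%). The other libraries stood at 2.55 to 3.01, with 32.63% to 38.15% rRNA. Whether the histone calls come from this link was not tested.

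Calls for further lists in wild type ended without N2_AL replicate 3. The SKN-1 and phase II list (median −0.45, 0 of 17 passing and 1 lower adjusted over the list alone, limma camera adjusted p = 0.011, and adjusted p = 0.933 with an estimated correlation) then had a median near 0 and an adjusted p of 0.281. Glutathione S-transferases (median −0.60, then −0.07) had an adjusted p of 0.437 in the same fit by limma camera. Autophagy genes (median 0.16, 0 of 26 passing, 0 adjusted over the list alone, limma camera adjusted p = 0.0208, and adjusted p = 0.933 with an estimated correlation) then had 0.632. Trehalose and glycogen genes (0.30, 0 of 13 passing, 0 adjusted over the list alone, limma camera adjusted p = 0.0429, and adjusted p = 0.933 with an estimated correlation) and germ line markers (0.17, 0 of 28 passing, 0 adjusted over the list alone, limma camera adjusted p = 0.0393, and adjusted p = 0.954 with an estimated correlation) turned direction, with adjusted p of 0.529 and 0.504. Vitellogenin genes (median −0.77, 0 of 6 passing, 0 adjusted over the list alone) were not called (limma camera adjusted p = 0.152), and were called lower without it (1.54e-05). Other lists called only without it, by limma camera adjusted p, were saposin-like proteins (median −0.35 turned to 0.52, 0.000495), the propionate shunt (−0.43, 0.000325), beta-oxidation (−0.24, 0.00457), fatty acid synthesis (−0.16, 0.00599) and UDP-glucuronosyltransferases (−0.06, 0.0337). None of these 6 calls, vitellogenins included, held with an estimated correlation, where the adjusted p was 0.714 for the propionate shunt, 0.848 for UDP-glucuronosyltransferases and 0.72 for the others.

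The count of 159 genes in wild type moved with single libraries. It was 24 without N2_DR replicate 2, 38 without N2_DR 3, 56 without N2_DR 1, 96 without sek1_DR 2, 98 without sek1_AL 2, 100 without sek1_AL 1 and 406 without N2_AL 3, and 0 genes passed in edgeR when the fit held only these 6 libraries (945 at an unadjusted p under 0.05). Of 40 named genes that passed, 11 passed in all 12 fits that left out 1 library (cpr-2, clec-60, clec-52, aqp-1, cutl-8, sysm-1, col-94, cth-1, cyp-35C1, cld-9 and F46F2.3), and all 40 kept their sign. Many were named for large changes without overlap between the groups, or for a small p, in these same data. A kept sign was largely set by that choice. With offsets for exon length, 128 genes rose and 158 fell. The excess of falls did not hold in every fit. Without N2_AL 3, 182 rose and 224 fell, and without N2_AL 3 and N2_DR 3, 175 rose and 154 fell. Without all libraries numbered 3, 455 rose and 382 fell.

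DR in sek-1(km4) asked what the same change of diet did without SEK-1. Here cpr-2 rose from 2.13 ± 0.711 to 86.2 ± 28.1 CPM (5.34 ± 0.41, edgeR adjusted p = 0.000396) and aqp-1 rose from 14.7 ± 2.3 to 55.2 ± 3.7 CPM (1.91 ± 0.21, edgeR adjusted p = 0.00357). The near-identical pud-1.1 (2.95) and pud-1.2 (2.70), given as uncertain, rose as well, with the fatty acid and retinol binding protein gene far-7 (2.14 ± 0.40) and F15E11.1 (2.03 ± 0.38). Of genes with a mean of at least 5 CPM and no overlap between the groups, the largest falls were in folt-2 (−3.70 ± 0.55), col-183 (−3.42 ± 0.47), col-93 (−3.12 ± 0.52), far-3 (−2.82 ± 0.37), F46F2.3 (−2.77 ± 0.30) and col-98 (−2.58 ± 0.34). In all, 25 genes rose and 41 fell in the mutant on DR. These counts use a spread shared with the N2 libraries, which are not in this contrast, and 2165 genes passed when only these 6 libraries were fitted. They therefore do not show a small response.

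Among collagens 6 of 125 fell and 0 rose in sek-1(km4) (33 of 126 fell without N2_AL 3), with a median of −0.62, and 27 fell and 1 rose adjusted over the list alone (limma camera adjusted p = 2.42e-18, and adjusted p = 0.903 with an estimated correlation). Examples were col-94 (−2.13) and col-103 (−1.91). In the propionate shunt, which degrades propionyl-CoA without vitamin B12, acdh-1 fell from 56.2 ± 10.7 to 10.2 ± 6.08 CPM (−2.45 ± 0.42, edgeR adjusted p = 0.0325). The other 4 measured shunt genes did not pass, and 4 of 5 were lower adjusted over the list alone, or over all genes without N2_AL 3 (limma camera adjusted p = 3.63e-06, and adjusted p = 0.353 with an estimated correlation). The p38-dependent effectors were not called in the mutant, with 0 of 18 passing, 2 lower adjusted over the list alone and a median of −0.34 (limma camera adjusted p = 0.0713).

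N2_AL 3 is not a library of this contrast, and it acts here only through the shared spread, the filter and the scaling. Leaving out N2_AL 3 raised the counts of members that fell on DR in the mutant from 0 to 17 of 28 germ line markers, 0 to 9 of 13 eggshell markers, 0 to 10 of 33 proteasome subunits, 0 to 8 of 81 ribosomal proteins and 1 to 5 of 31 glutathione S-transferases. Of the 31 pals genes tested there 8 rose, against 0 of 30 with it. With all libraries, germ line markers ranked lower, with a median of −0.41 and 0 of 28 passing or lower adjusted over the list alone (limma camera adjusted p = 1.49e-07, and adjusted p = 0.933 with an estimated correlation). Eggshell markers did too, with a median of −0.63 and 0 of 13 on either count (limma camera adjusted p = 2.35e-05, and adjusted p = 0.903 with an estimated correlation). Vitellogenin genes had a median of −1.02, 0 of 6 passing and 2 lower adjusted over the list alone (limma camera adjusted p = 0.00305, and adjusted p = 0.933 with an estimated correlation). The pals genes ranked higher, with a median of 0.80, 0 of 30 passing and 5 higher adjusted over the list alone (limma camera adjusted p = 6.29e-08, and adjusted p = 0.903 with an estimated correlation). Lysozymes (12 genes, median −0.51, 0 passing, 3 lower adjusted over the list alone, limma camera adjusted p = 0.0193, and adjusted p = 0.933 with an estimated correlation) lost the call without N2_AL 3 (0.0844) or without sek1_AL 3. Ribosomal proteins (median −0.23, adjusted p = 0.00397) and proteasome subunits (median −0.20, adjusted p = 0.00193) were called lower by limma camera with 0 members passing on either count, with 0.954 and 0.903 as the adjusted p with an estimated correlation. Glutathione S-transferases (median −0.31) had 1 of 31 fall, gst-29 at −1.50, and 2 adjusted over the list alone (limma camera adjusted p = 0.00462, and adjusted p = 0.933 with an estimated correlation), a call lost without sek1_AL 3.

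A further 5 lists were called in the mutant on DR by limma camera, each with 0 members passing over all genes and adjusted p = 0.933 with an estimated correlation. Insulin-like peptides (median 0.45, adjusted p = 0.0324) and p38 components (0.40, 0.0333) ranked higher, while SKN-1 and phase II genes (−0.12, 0.0324, with 2 lower adjusted over the list alone), epidermal antimicrobial peptides (−0.46, 0.0393) and body wall muscle markers (−0.21, 0.0464) ranked lower. Each of the 5 lost its call without at least 1 library. Without N2_AL 3, 5 members each of the SKN-1, epidermal peptide and muscle lists fell, against 0 with it, and glycolysis (0.0251) and oxidative phosphorylation (0.017) were called lower by limma camera adjusted p, and adjusted p = 0.848 with an estimated correlation for both. The gene count of 66 was 6 without sek1_AL 1 or sek1_DR 2, 13 without sek1_AL 2, 16 without sek1_DR 3, 38 and 40 without N2_DR 1 and N2_DR 2, 2239 without N2_AL 3, and 2165 when only these 6 libraries were fitted. Of 16 named genes that passed, cpr-2, aqp-1 and F46F2.3 passed in all 12 fits that left out 1 library.

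The diet response was then compared between the genotypes, which share no library here. Of the genes that passed in each, 13 rose in both and 27 fell in both, 0 moved in opposite directions, and independent lists of these sizes would share 0.0907 and 0.297. Chosen after their values were seen, examples are the alcohol dehydrogenase gene adh-1 (1.48 in N2 and 1.54 in the mutant), argk-1 (−3.71 and −4.37), ugt-53 (−3.16 and −2.54), cbl-1 (−1.68 and −1.84) and cth-1 (−2.995 and −2.13). All 53 genes that rose in wild type had a positive log2 fold change in sek-1(km4), with medians of 1.23 and 0.74. Of the 106 that fell, 94 had a negative one, with medians of −1.92 and −1.16. Of the 25 genes that rose in sek-1(km4), 22 had a positive value in N2, with medians of 1.6 in the mutant and 1.18 in N2. All 41 that fell in the mutant were negative in N2, with medians of −2.1 and −1.58. A gene chosen for passing in 1 genotype tends to have a larger value there, so these medians do not show a weaker response in either genotype. Across all 14611 genes the correlation of log2 fold changes was r = 0.118 (rho 0.166, jackknife SE 0.344 over libraries, genes not being independent replicates). It was 0.382 without N2_AL 3 and −0.00881 without sek1_AL 2, and unchanged simulated groups gave at most 0.0243. That simulation drew each gene independently and held no variation shared across the genes of a library. Its values therefore spread too little to judge this r, which was smaller than its jackknife SE. The shared count of 40 ranged from 6 without sek1_AL 1 to 209 without N2_AL 3.

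**Figure D4:**
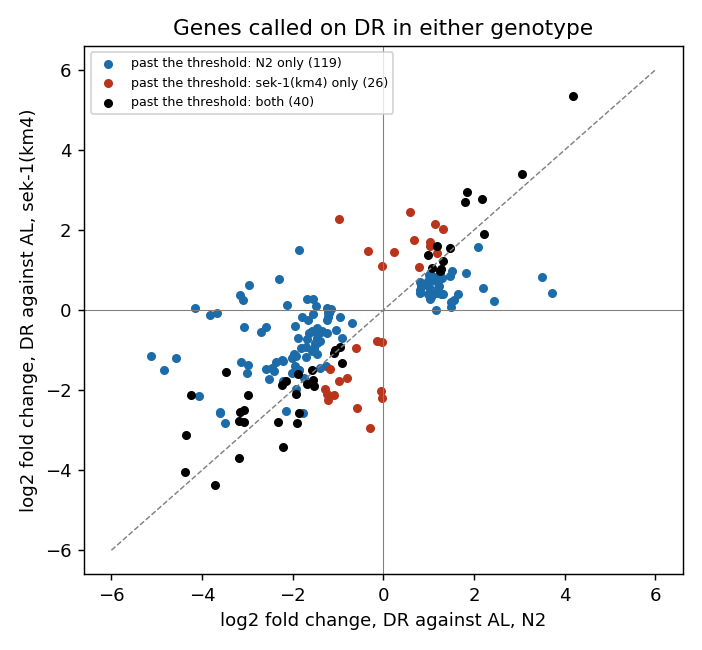
Log2 fold change on DR against AL in N2 (horizontal axis) and in sek-1(km4) (vertical axis) for genes that passed in either genotype, each gene a point and the dashed line marking equality. The 40 genes that passed in both lie in the lower left and upper right, 27 lower and 13 higher in both.

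Loss of SEK-1 under full feeding changed 2550 genes, or 17.5% of those tested, with 1860 higher and 690 lower in sek-1(km4). Among the genes that fell, C17H12.8 went from 59.9 ± 11.4 CPM in N2 to 0.116 ± 0.0663 CPM (n = 3 per group, edgeR adjusted p = 9.39e-07), dod-24 from 20.6 ± 2.87 to 0.197 ± 0.0832 CPM (−6.68 ± 0.51), and the lysozyme gene lys-2 from 87.8 ± 33.4 to 1.65 ± 0.093 CPM (−5.73 ± 0.35, edgeR adjusted p = 2.91e-06). Among the genes that rose, the cuticlin gene cut-2 went from 0.386 ± 0.149 to 33.4 ± 5.23 CPM (6.51 ± 0.31, edgeR adjusted p = 9.39e-07), the lipocalin-related gene lpr-4 from 0.104 ± 0.071 to 15.3 ± 2.42 CPM and the collagen gene dpy-7 from 0.624 ± 0.156 to 18.97 ± 0.543 CPM (4.89 ± 0.29, edgeR adjusted p = 2.82e-06).

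Further rises on AL were in ZK180.5 (5.96), col-144 (5.86), lpr-5 (5.75), T19C3.3 (5.51), col-10 (5.404), cut-5 (5.39), the lipase-related gene lips-11 (5.07) and F41F3.3 (5.05). Further falls were in clec-47 (−6.64 ± 0.61), and in the near-identical pairs C08F11.12 (−8.11) and Y45F10C.2 (−7.75), and Y19D10A.9 (−6.41) and F56A4.2 (−6.35), whose separate values are uncertain. C54C8.12 stood at 22.4 ± 22.3 CPM in N2_AL and 0.0246 ± 0.0213 CPM in sek1_AL, and nlp-39 at 25.1 ± 24.9 and 0.04 ± 0.0386 CPM, levels under the limit of 3 counts in the mutant. Where a group mean lay at or under that limit in its libraries, as for these genes, C17H12.8 in sek-1(km4) and lpr-4 in N2_AL, no fold is given. Of the genes always named, sysm-1, irg-5 and irg-4 (all at or under that limit in the mutant) and clec-67 (−3.37, edgeR adjusted p = 0.0365) fell, while pmk-1 (0.71 ± 0.17), sod-3 (1.86 ± 0.35) and hlh-30 (0.88 ± 0.27, edgeR adjusted p = 0.0472) rose. Values that did not pass were acs-2 −0.29, fat-7 0.60, mtl-1 −1.28, vit-2 0.06, gst-4 −0.36, ins-7 0.49, daf-16 0.42, skn-1 0.36, pha-4 −0.49 and lipl-4 −0.48.

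All 18 p38-dependent effectors passed on AL, 16 lower and 2 higher in the mutant, with the same counts adjusted over the list alone and a median of −4.73. That median rests on fitted values, and 11 of the 18 had a mean sek1_AL count under 4 times the limit of 3. The members that rose were clec-60 (4.34 ± 0.50, edgeR adjusted p = 0.000168) and T19D12.4 (1.399). The list was called by limma camera (adjusted p = 1.28e-31) and is the list call that held with an estimated correlation (adjusted p = 0.0041). The components of the pathway ranked higher, with 4 of 7 up on both counts, tir-1 (1.80 ± 0.26), pmk-3 (1.51 ± 0.25), pmk-2 (1.08 ± 0.19) and pmk-1 (limma camera adjusted p = 0.00993, and adjusted p = 0.933 with an estimated correlation). Of 8 DAF-16 targets lowered by low insulin signalling 3 fell and 1 rose on both counts, dod-22, dod-24 and dod-17 falling, of which dod-22 and dod-24 are also p38-dependent effectors (limma camera adjusted p = 0.00461, and adjusted p = 0.903 with an estimated correlation). That call ended without N2_AL 3 (0.19).

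Of 125 collagen genes 52 rose, 7 fell and 66 did not pass on AL, with a median of 1.28, and 61 rose and 9 fell adjusted over the list alone. Examples were col-107 (4.55 ± 0.30) and col-121 (3.13 ± 0.25), and limma camera gave an adjusted p of 5.27e-11, and adjusted p = 0.903 with an estimated correlation. Neuronal markers had 10 of 27 rise and 0 fall (12 rose adjusted over the list alone, and 18 over all genes without N2_AL 3), such as unc-13 (1.87 ± 0.38), rab-3 (1.69 ± 0.30) and unc-31 (1.39 ± 0.23). For this list limma camera gave an adjusted p of 0.00249, and adjusted p = 0.903 with an estimated correlation. Intestinal markers had 7 of 19 rise and 1 fall (9 and 2 adjusted over the list alone, median 0.60, limma camera adjusted p = 0.0496, and adjusted p = 0.933 with an estimated correlation), and lost the call without N2_AL 3 (0.334, with 4 lower), sek1_AL 1, sek1_AL 2 or sek1_DR 2. UDP-glucuronosyltransferases went both ways, 7 rising and 13 falling of 56 (12 and 18 of 57 without N2_AL 3, 9 and 15 adjusted over the list alone, limma camera adjusted p = 0.0193, and adjusted p = 0.933 with an estimated correlation), and lost the call without N2_AL 1, N2_AL 2 or sek1_AL 1. Lysozymes also went both ways and were not called, 5 rising and 3 falling of 12 (7 and 3 adjusted over the list alone, limma camera adjusted p = 0.738). Without N2_AL 3, 8 rose and 3 fell of 13, and the median went from 1.46 to 2.2.

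Several further lists ranked lower on AL, some of them in part with N2_AL replicate 3. Histone genes had 12 of 71 fall and 1 rise (14 and 1 adjusted over the list alone, median −0.70 and −0.43 without that library). Limma camera gave an adjusted p of 1.49e-07, and adjusted p = 0.933 with an estimated correlation. Ribosomal proteins had 2 of 81 fall (0 adjusted over the list alone, median −0.78, and without that library −0.15 with 7 lower). By limma camera the adjusted p was 6.3e-09, and adjusted p = 0.933 with an estimated correlation. Oxidative phosphorylation genes had 2 of 58 fall (0 adjusted over the list alone, median −0.51, and without it −0.11 with 6 lower). The camera test in limma had an adjusted p of 7.1e-05, and adjusted p = 0.933 with an estimated correlation. Mitochondrially encoded genes had 0 of 12 pass on either count (median −1.3 and 0.05 without it), with limma camera adjusted p = 0.0438, and adjusted p = 0.933 with an estimated correlation, and epidermal antimicrobial peptides had 3 of 14 fall on both counts. For this list limma camera gave an adjusted p of 0.0393, and adjusted p = 0.933 with an estimated correlation. Without N2_AL 3 the adjusted p of these 2 lists was 0.645 and 0.835 by limma camera, and the median of the epidermal peptides went from −0.51 to 0.42, with 6 then higher. Germ line markers had 3 of 28 fall, such as pgl-3 (−0.79), and 0 adjusted over the list alone. Limma camera gave an adjusted p of 0.00435, and adjusted p = 0.933 with an estimated correlation. Eggshell markers had 2 of 13 fall on both counts, such as cpg-3 (−0.95). By limma camera the adjusted p was 0.0193, and adjusted p = 0.933 with an estimated correlation. Proteasome subunits had 1 of 33 fall (7 without N2_AL 3) and 0 adjusted over the list alone. The camera test in limma had an adjusted p of 0.00216, and adjusted p = 0.903 with an estimated correlation. The germ line and eggshell calls ended without N2_AL 1, N2_AL 2 or sek1_AL 3. Without N2_AL 3 they were stronger, with germ line markers at a median of −0.49 (−0.26 with it), 18 lower and a limma camera adjusted p of 2.71e-07, and eggshell markers at −0.70 (−0.42 with it), 11 lower and 2.84e-05, and adjusted p = 0.72 with an estimated correlation for both. Lists called on AL only without N2_AL 3, by limma camera adjusted p, were saposin-like proteins (14 of 23 higher, 0.00232), pals genes (12 of 31 higher, 0.045), heat shock genes (6 of 12 higher, 0.045), glycolysis (9 of 19 lower, 0.0105), the glyoxylate cycle (4 of 10 lower, 0.0352) and the propionate shunt (2 of 5 lower, 0.0417). With an estimated correlation none of these held, the adjusted p being 0.72 for saposins and the propionate shunt, 0.839 for pals genes and glycolysis, 0.782 for heat shock genes and 0.848 for the glyoxylate cycle. For the histone call, N2_AL 2 and N2_AL 3 again held both the high histone levels and the high rRNA shares.

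The count of 2550 was 1531 without sek1_AL 3, 1649 without sek1_AL 2, 5458 without N2_AL 3 (3461 higher and 1997 lower), and 1187 when only these 6 libraries were fitted. The split of 1860 higher and 690 lower was 2110 and 1830 with DESeq2 and 1994 and 2566 with offsets for exon length, which shifted the median log2 fold change of all genes by −0.142.

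On DR, 5768 genes (39.5%) differed between the strains, 3631 higher and 2137 lower in sek-1(km4). C17H12.8 (edgeR adjusted p = 1.12e-06) and dod-24, both at the limit of 3 counts in the mutant, and lys-2 (−5.77 ± 0.37, edgeR adjusted p = 3.98e-06) were again lower, and cut-2 (5.75 ± 0.30, edgeR adjusted p = 1.12e-06), lpr-4 (6.63 ± 0.50), ZK180.5 (6.24), col-10 (5.63), F41F3.3 (5.47) and F53F1.4 (5.10) were higher. The uncertain pair Y45F10C.2 (−7.85) and C08F11.12 (−7.84) fell with Y19D10A.9, at the limit in the mutant. Neither C54C8.12 nor nlp-39 is given a fold, with 0 counts of C54C8.12 and 0.012 ± 0.0208 CPM of nlp-39 in sek1_DR against 10.6 ± 2.2 and 11.9 ± 3.55 CPM in N2_DR. The genotype effect on AL and on DR shared 1729 genes higher and 504 lower in both, against 462 and 101 for independent lists, and the log2 fold changes correlated at r = 0.709 across genes (rho 0.708, no shared library).

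Of 18 p38-dependent effectors 14 fell and 2 rose on DR, over all genes and adjusted over the list alone, with a median of −3.09 (limma camera adjusted p = 1.9e-13, and adjusted p = 0.0923 with an estimated correlation). Among the effectors clec-67 and sysm-1 fell to levels under the limit of 3 counts, and irg-4 did not pass. Of 125 collagens 64 rose and 9 fell (69 and 9 adjusted over the list alone, median 1.71), including col-107 (5.05 ± 0.31), col-144 (5.08) and dpy-7 (4.23). For this list limma camera gave an adjusted p of 2.23e-09, and adjusted p = 0.903 with an estimated correlation. Neuronal markers had 14 of 27 rise and 0 fall (15 adjusted over the list alone), such as rab-3 (2.26) and unc-31 (2.26). Limma camera gave an adjusted p of 0.00514, and adjusted p = 0.903 with an estimated correlation. Pharyngeal markers had 8 of 12 rise and 0 fall on both counts (median 1.54), such as tnt-4 (1.62 ± 0.29) and myo-5 (1.45 ± 0.27). By limma camera the adjusted p was 0.0317, and adjusted p = 0.903 with an estimated correlation. That call was lost without N2_AL 3 (0.0511) or without N2_DR 3. The pals genes had 6 of 30 rise and 0 fall (5 adjusted over the list alone, and 17 of 31 over all genes without N2_AL 3), with limma camera adjusted p = 0.0393, and adjusted p = 0.933 with an estimated correlation, a call that was lost without N2_DR 3 or sek1_DR 3.

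Germ line markers fell in 23 of 28 cases and rose in 0 on both counts, with a median of −0.92 and examples puf-5 (−1.24 ± 0.20) and pgl-3 (−1.27 ± 0.20), and limma camera gave an adjusted p of 9.33e-10, and adjusted p = 0.903 with an estimated correlation. Eggshell markers fell in 12 of 13 cases on both counts, such as egg-1 (−1.33) and cpg-3 (−1.36). The camera test in limma had an adjusted p of 2.56e-06, and adjusted p = 0.903 with an estimated correlation. Proteasome subunits fell in 19 of 33 cases (21 adjusted over the list alone, and 32 over all genes without N2_AL 3), such as pas-6 (−0.69), pbs-6 (−0.76) and rpn-8 (−0.61). For this list limma camera gave an adjusted p of 2.56e-06, and adjusted p = 0.903 with an estimated correlation. Glycolytic genes fell in 8 of 19 cases and rose in 1 on both counts, with pgk-1 (−1.03) and gpd-1 (−1.02) falling and aldo-1 (1.34) rising. Limma camera gave an adjusted p of 0.0193, and adjusted p = 0.933 with an estimated correlation. The propionate shunt fell in 4 of 5 cases on both counts, acdh-1 from 71.2 ± 16 to 10.2 ± 6.08 CPM (−2.79 ± 0.42, edgeR adjusted p = 0.000637). By limma camera the adjusted p was 0.0172, and adjusted p = 0.903 with an estimated correlation. Lysosomal proteases fell in 11 of 23 cases and rose in 5 on both counts, asp-5 (−3.04), asp-12 (−2.99) and asp-14 (−2.67) falling and asp-17 (2.50) rising. The camera test in limma had an adjusted p of 0.0131, and adjusted p = 0.933 with an estimated correlation. That call was lost without N2_AL 3 (0.051) or without sek1_DR 3.

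Ribosomal proteins had 4 of 81 fall and 2 rise (0 adjusted over the list alone, median −0.38, limma camera adjusted p = 0.000318, and adjusted p = 0.954 with an estimated correlation), and without N2_AL 3, 67 fell and 3 rose. Oxidative phosphorylation genes had 8 of 58 fall and 2 rise (6 and 1 adjusted over the list alone, limma camera adjusted p = 0.00161, and adjusted p = 0.933 with an estimated correlation), and without N2_AL 3, 40 fell and 4 rose. Of the genes always named, ins-7 (3.77 ± 1.25, edgeR adjusted p = 0.0323), pha-4 (1.44 ± 0.44, edgeR adjusted p = 0.0218), pmk-1 (0.65 ± 0.17), sod-3 (1.29) and hlh-30 (0.77) rose and irg-5, mtl-1 (−1.50) and lipl-4 (−1.38) fell. Acs-2 (−0.01), fat-7 (0.68), vit-2 (0.23), gst-4 (−0.48), daf-16 (0.28) and skn-1 (0.30) did not pass. The count of 5768 was 3785 without sek1_DR 2, 9590 without N2_AL 3 and 8760 when only these 6 libraries were fitted. With offsets for exon length 3304 genes were higher and 4577 lower, with a shift of −0.232 in the median of all genes, and the median also shifted by −0.104 with RLE size factors and −0.105 with DESeq2.

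The interaction asked whether the diet response differed between the genotypes. The 5 genes with the smallest p were clec-52 (−2.21 ± 0.35), which rose on DR in N2 from 4.89 ± 0.298 to 26.5 ± 5.36 CPM and stood at 7.49 ± 0.788 and 8.69 ± 2.98 CPM in the mutant, the heme transporter gene hrg-1 (1.80 ± 0.29), cyp-36A1 (1.84 ± 0.30), K11H12.4 (3.34 ± 0.54) and K08D8.4 (3.36 ± 0.55). Hrg-1 stood at 2.75 ± 0.58 CPM in N2_AL, 2.17 ± 0.172 in N2_DR, 3.75 ± 0.639 in sek1_AL and 10.3 ± 0.331 in sek1_DR. None of the 5 passed (edgeR adjusted p = 0.19 for each), and 0 genes passed in edgeR, with 1302 at an unadjusted p under 0.05, 50 passing in DESeq2 and 1365 in limma voom with sample weights. Without N2_AL 3, 13 genes passed, these 5 among them (edgeR adjusted p of 0.0301 for clec-52 and cyp-36A1, 0.0432 for hrg-1, 0.0414 for K11H12.4 and 0.0105 for K08D8.4). The p38-dependent effectors were not called (median 0.35, limma camera adjusted p = 0.154). Neither irg-4 nor sysm-1 passed. Without N2_AL 3 the effector list was called (median 0.43, limma camera adjusted p = 0.0403, and adjusted p = 0.72 with an estimated correlation). For 16 lists the camera test of the interaction was called, and 0 of them held with an estimated correlation or in fry.

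DR in wild type and loss of SEK-1 on AL were compared, as fixed in advance, to ask whether they change the same genes. They share the N2_AL libraries. Genes that passed in both were 26 higher and 46 lower in the same direction, with 5 and 9 in opposite directions, against 6.75 and 5.01 for independent lists. Lys-2, sysm-1, cld-9, irg-4 and cnc-4 were among those lower in both, and clec-60, aqp-1, cutl-8 and tir-1 among those higher in both. The log2 fold changes correlated at r = 0.331 across genes (rho 0.326, jackknife SE 0.185), and unchanged groups simulated against the same controls gave a mean r of 0.524. The covariance was 0.286 against 0.0998 simulated, a difference of 0.187. The mean variance of N2_AL over 3 was 0.24 (log2 CPM), and sharing that group mean alone would bring a covariance of about that size. The simulation used 1 dispersion per gene for all groups, while this variance was 0.0495 in N2_DR, 0.0376 in sek1_AL and 0.0378 in sek1_DR. Its covariance is thus too low for these controls, and most of the excess may come from them. The 3 N2_AL libraries cannot be split, so neither r nor the covariance shows a shared response. Noise in the shared libraries also moves a gene the same way in both contrasts. The 2 lists are thus not independent, and the shared counts and genes do not show such a response either. The shared count of 72 ranged from 14 without N2_DR 2 to 188 without N2_AL 3. DR in the mutant and loss of SEK-1 on AL, which share the sek1_AL libraries with opposite sign, had 19 genes passing in the same direction and 13 in opposite directions. Their log2 fold changes correlated at r = 0.0863, against a simulated mean of −0.486, with a covariance of 0.0521 against −0.0903. The simulation again used 1 dispersion per gene for all groups. The variance of sek1_AL over 3 was 0.0376, so the simulated values are here probably too negative. The gap to them therefore shows no shared response.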

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

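The camera tests below were fixed in advance, and the value without N2_AL replicate 3 was read only after that library had been seen to stand apart. A result was taken up here when a test of the difference between the genotypes' diet responses was called. This held for 16 lists in the genotype by diet interaction (limma camera, n = 3 per group), and none held with an estimated correlation, where each adjusted p was 0.903 or 0.933. Positive values are medians of the log2 difference, higher meaning a more positive diet response in sek-1(km4).

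Germ line and oocyte markers had a median of −0.59 (adjusted p by limma camera 1.03e-10) and eggshell markers −0.849 (2.56e-06). The proteasome stood at −0.234 (0.000581), lysosomal proteases at −0.457 (0.0172), lysozymes at −0.394 (0.0324) and vacuolar ATPase subunits at −0.171 (0.0429). In metabolism, the glyoxylate cycle had a median of −0.388 (limma camera adjusted p 0.0317), trehalose and glycogen genes −0.39 (0.0172), glycolysis −0.289 (0.0429) and the propionate shunt −0.203 (0.0317). Histones stood at 0.655 (1.7e-09), epidermal antimicrobial peptides at 1.49 (0.000145), pharyngeal markers at 0.71 (0.0031), insulin-like peptides at 0.842 (0.0193), mitochondrially encoded genes at 1.34 (0.0393) and DAF-16 targets lowered by low insulin signalling at 1 (0.0393), all by limma camera. Without N2_AL replicate 3, 7 of the 16 calls were kept (limma camera adjusted p). These were germ line markers (median −0.38, 3.21e-07), eggshell markers (−0.643, 5.91e-05), histones (0.432, 5.15e-07), the proteasome (−0.341, 2.12e-07), lysozymes (−1.12, 5.1e-05), epidermal peptides (0.469, 0.0117) and the pharynx (0.69, 0.00234). The other 9 were lost, among them lysosomal proteases (−0.628, 0.112), vacuolar ATPase subunits (−0.158, 0.292), the glyoxylate cycle (−0.064, 0.714), trehalose and glycogen genes (−0.134, 0.693), glycolysis (−0.317, 0.359), the propionate shunt (−0.388, 0.184) and insulin-like peptides (0.0914, 0.365). Of those 9, DAF-16 targets lowered by low insulin signalling (−0.136, 0.229) and mitochondrially encoded genes (−0.099, 0.807) also turned sign. A further 8 lists were called only without that library. They were ribosomal proteins (0.378 turned to −0.316, limma camera adjusted p = 6.5e-09), oxidative phosphorylation (0.222 turned to −0.276, 0.00131), saposin-like proteins (0.042 turned to −0.833, 1.58e-06), body wall muscle (0.451, 1.59e-05), cytochrome P450s (0.141, 0.00909), fatty acid synthesis (0.16, 0.0147), regulators reported for lifespan under DR (−0.168 turned to 0.145, 0.0251) and p38-dependent effectors (0.434, 0.0403). With an estimated correlation none of the calls without that library held, neither the 7 nor the 8, with adjusted p from 0.714 to 0.848. The histone call was kept in a fit that still held N2_AL 2 and sek1_DR 3. There histone levels (3.56 and 3.38 log2 CPM) and rRNA shares (50.95% and 45%) were both high, and this link was not tested.

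Chance could not be excluded for these list calls. Of 100 groupings of the 12 libraries, the real one among them and the others with diet regrouped within each genotype, 53 called at least as many lists as the 16 of the real groups (highest other 23). A regrouping can keep part of a real difference, so this share does not decide either way. For genes the real count was 0, which every regrouping reaches whatever its libraries (100 of 100, highest other 1), so the gene count bears on neither answer.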

How the results depend on the processing

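The settings beyond those listed in advance were chosen after the data were seen. Of named-gene values under other settings, 9215 kept their side of the threshold, 596 passed only there, 437 no longer passed and 133 changed sign without passing in either setting, and of list values 1416 were unchanged, 327 were lost and 5 turned direction. Counts below are genes for DR in N2, DR in sek-1(km4), genotype on AL, genotype on DR and the interaction, and then the genes shared by both diet responses and by DR in N2 with genotype on AL, where they moved by over 1.5 times. In simulated counts edgeR recovered 19.4% of 2-fold changes for DR in N2 and 83.3% of 4-fold changes, so many 2-fold changes would be missed here, and depth was not varied. The cause of each move below was not tested.

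The overlap of the DR response in N2 and in sek-1(km4) and the overlap of the DR response in N2 and the sek-1(km4) effect on AL are the 2 shared counts, and the sek-1 value is the log2 fold change of the sek-1 transcript level: sek-1(km4) against N2 on AL, or sek-1 transcript level: sek-1(km4) against N2 on DR. The replicate block gave 246 and 183 genes for the diet responses, 1 for the interaction and shared counts of 83 and 112. Same-number correlations ran from −0.0715 to 0.388, so the numbers did not meet the rule of over 0.1 for every pair and were not taken as pairs. All pairs numbered 1 or 3 correlated at 0.117 to 0.388, each above the largest value with another number, while those numbered 2 ran from −0.0715 to 0.14. The 4 libraries numbered 3 also shared a negative trend with exon length (Spearman −0.557, −0.397, −0.415 and −0.37), so an effect shared by replicate number is a hint from the data and not the design. The block with length offsets gave 488, 728, 4932 and 1 (interaction), and shared counts of 209 and 222. Length offsets alone gave 286, 272 and 4560, shared counts of 79 and 139 and a sek-1 transcript value of −0.05477 on AL. DESeq2 gave 533, 726, 3940 and 50 (interaction), and shared counts of 170 and 218. With voom weights the counts were 1050, 6334, 6942, 10914 and 1365, shared counts 648 and 485 and the sek-1 value on AL −0.3245. Without a low-count filter DR in sek-1(km4) gave 114 and the interaction 6, and the correlation of DR in N2 with genotype on AL was 0.592. Fits of only the 6 libraries compared gave 0, 2165, 1187 and 8760. Lists called were 0, 0, 1, 0 and 0 with an estimated correlation and 2, 1, 6, 8 and 0 with fry. Without N2_AL 3 and N2_DR 3 the counts were 329, 3295, 6693, 8985 and 10, shared counts 211 and 184, the sek-1 value on AL −0.3181 and on DR −0.2946, and the germ line list in N2 turned direction (limma camera adjusted p = 0.355). Without all libraries numbered 3 they were 837, 4346, 6360, 9193 and 495, shared counts 541 and 436, the sek-1 value on AL −0.3105, and the germ line list turned (0.301). Leaving out 1 library gave 24 to 406, 6 to 2239, 1531 to 5458, 3785 to 9590 and 0 to 13 genes, and lists of 16 to 18, 13 to 17, 11 to 17, 11 to 14 and 11 to 17. Shared counts then ranged from 6 to 209 and 14 to 188, correlations from −0.00881 to 0.382 and 0.31 to 0.497, and the sek-1 value from −0.3151 to 0.5022 on AL and −0.3672 to −0.153 on DR. Without N2_AL 3 the lists that turned direction in N2 were trehalose and glycogen (adjusted p from 0.00344 to 0.529 over the 12 fits), the list ribosomal proteins: DR against AL in N2 (1.65e-14 to 0.504) and germ line (0.00239 to 0.504, limma camera).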

Other observations

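The biology in the first 2 paragraphs uses tests fixed in advance. Every test of an explanation in the later paragraphs was chosen after the pattern had been seen, although the fit without N2_AL replicate 3 was itself listed in advance. Several gene families of detoxification and immunity had members that passed between the genotypes on DR without a call for the list. Of 90 C-type lectins 26 rose and 21 fell in sek-1(km4) (28 and 23 adjusted over the list alone, limma camera adjusted p = 0.238), against 16 and 14 on AL. Of 50 cytochrome P450s 13 rose and 11 fell (0.985), of 31 glutathione S-transferases 10 rose and 2 fell (0.783), and of 56 UDP-glucuronosyltransferases 11 rose and 14 fell (0.171, all limma camera). Saposin-like proteins rose in 5 of 23 cases (0 adjusted over the list alone, 0.987), flavin-containing monooxygenases in 1 of 5 (0.766) and cytosolic heat shock genes in 4 of 12 (0.536). Unfolded protein response genes had 3 of 16 rise and 3 fall (0.325), and DAF-16 targets raised by low insulin signalling had 3 of 17 rise and 7 fall (0.172). Without N2_AL replicate 3 the counts of risen and fallen genes were 18 and 18 for UDP-glucuronosyltransferases, 13 and 4 for glutathione S-transferases, 4 and 7 for unfolded protein response genes, 6 and 2 for saposin-like proteins, 4 and 2 for heat shock genes, 2 and 0 for flavin-containing monooxygenases, and 28 and 16 for C-type lectins on AL.

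Metabolic lists without a call on DR between the genotypes included fatty acid beta-oxidation (9 of 27 rose and 4 fell, limma camera adjusted p = 0.987), fatty acid synthesis (3 of 19 rose, 0.726), the glyoxylate cycle (3 of 10 fell, 0.0521), vacuolar ATPase subunits (1 of 20 fell, 0.194) and lysosomal lipases (2 of 7 rose and 1 fell, 0.747). Trehalose and glycogen genes had 2 of 13 rise and 3 fall (0.235), and 3 and 6 without N2_AL 3. Vitellogenins (0 of 6 passing, 0.536) and mitochondrially encoded genes (0 of 12, 0.619) were not called either. Autophagy genes had 3 of 26 rise and 2 fall (0.887), and regulators reported for lifespan under DR had 4 of 21 rise and 1 fall (0.925). Sperm markers had 2 of 9 rise and 1 fall (0.99), intestinal markers 10 of 19 rise and 3 fall (0.11), and body wall muscle markers 7 of 20 rise and 0 fall (0.254, all limma camera). Without N2_AL replicate 3 the counts of risen and fallen genes became 12 and 8 for beta-oxidation, 7 and 2 for fatty acid synthesis, 1 and 5 for the glyoxylate cycle, 2 and 8 for vacuolar ATPase subunits, 7 and 6 for autophagy, 6 and 5 for lifespan regulators, 3 and 2 for sperm and 10 and 0 for body wall muscle. The cathepsin D-like protease gene asp-5 stood at 192.8, 227.4, 34.5 and 27.6 CPM in N2_AL, N2_DR, sek1_AL and sek1_DR.

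N2_AL replicate 3 stood apart from its group, and 3 technical explanations were tested. Removing the trend with exon length from each library raised its highest correlation with its group from 0.907 to 0.928 only, so that trend may be part of the difference, with 27.2% of the squared difference removed, but not all of it. Lower depth does not account for it, since the other N2_AL libraries thinned to its depth correlated at 0.989. A wrong genotype label does not either, with a median log2 CPM of p38-dependent effectors of 2.87 against 2.93 in the other N2_AL libraries and −1.79 in sek1_AL. No biological explanation was tested.

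Collagen genes were higher in sek-1(km4) on both diets. A trend with exon length does not account for this, since the larger of the adjusted p with length offsets was 5.6e-10 (limma camera), though without offsets the call did not hold with an estimated correlation on either diet (adjusted p = 0.903). More embryonic tissue in the mutant animals could account for part of it. The 23 embryo markers had a median log2 fold change of 0.9982 ± 0.2433 (bootstrap SE) on DR. Of these, 16 rose and 0 fell on DR, and 9 rose and 0 fell on AL. The largest rise on DR was in unc-86 (4.14), and elt-3 (1.63) also rose. Markers that did not pass on DR included end-3 (0.27), elt-7 (0.10) and lin-26 (0.01). Many such markers are also expressed in adult tissue, so this stays open. A lower share of germ line RNA alone does not explain why the collagen median exceeded that of body wall muscle markers (by 1.12 ± 0.336 on AL and 1.16 ± 0.277 on DR, bootstrap SE) and of neuronal markers on DR (0.914 ± 0.236). Other somatic values leave it open, with a smaller excess against the SE. These were neuronal markers on AL (0.61 ± 0.38), intestinal markers (0.68 ± 0.53 on AL, 0.63 ± 0.54 on DR) and pharyngeal markers (0.70 ± 0.41 on AL, 0.17 ± 0.378 on DR). The bootstrap takes genes as independent, so its SE may be too small.

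The p38-dependent effectors were lower on DR in N2. Neither N2_AL replicate 3 (adjusted p = 7.09e-19 without it) nor a trend with exon length (1.55e-14 with offsets, both limma camera) accounts for this, though with an estimated correlation the adjusted p was 0.0888 with all libraries and 0.102 without that library. A lower p38 activity on DR was not measured. The smaller fall in sek-1(km4) could come from a limit of detection, since 11 of 18 effectors had a mean sek1_AL count under 4 times the limit of 3 counts.

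The libraries of each comparison were also regrouped in all 10 ways. The real groups gave 159, 66, 2550 and 5768 genes (highest other 0 in each, 1 of 10 reaching the real count), and 10 regroupings cannot give a share under 0.05. For lists, 8, 7, 6 and 9 of 10 reached the real counts of 17, 15, 15 and 13 (highest other 22, 18, 22 and 24). The real groups are among the 10, and every other regrouping still holds most libraries of a real group together. Part of a real difference therefore remains in each, and these shares cannot tell whether the list calls are chance. Counts of called lists are not used as support.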
